A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

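Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed in fission yeast, Schizosaccharomyces pombe. The 3 tagged strains carried a C-terminal TAP tag (an affinity tag that binds IgG beads) on Fkh2, Sak1 or Sep1, and an untagged strain went through the same immunoprecipitation. Per the labels, each immunoprecipitation used chromatin from 60 mL of culture and 20 uL of IgG beads, with washes at 1 M and 500 mM NaCl. The Sep1-TAP culture had been treated with bortezomib, a proteasome inhibitor, at 1 mM for 45 min, per the labels; the dose could not be checked, and the labels give no treatment for the other cultures. Each of the 4 samples pools 2 biological experiments, per the labels, so each factor has 1 peak list and no replicate error can be computed.

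Per the submitters' processing notes, Bowtie2 2.1.0, SAMtools 0.1.18 and HOMER were used; the role of each, the HOMER version and the genome build are not given in the sources used here. Per the file headers, peaks were called by HOMER's findPeaks on each tagged library with the untagged library as control. The headers give a false discovery rate of 0.001, a required 4 fold over the control and 4 fold over the surrounding 10000 bp, and a Poisson p-value limit of 1e-04 against the control. Normalised tag counts in the deposited lists are a signal scaled by the authors to 10000000 tags per library. The control tags of each peak, the fold over the control and the fold over the local background are ratios and signals given per peak in the deposited files. The focus ratio is a deposited fraction and the findPeaks score a deposited score; neither entered a test. The deposited p-values against the control are the peak caller's own and were not reinterpreted. Scores, tag counts and folds were used only to describe, rank or filter peaks within 1 list, except that tag counts at shared peaks were compared between the Fkh2 and Sak1 libraries in a check for carried-over DNA.

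The library totals in the headers were 1042990 tags for Fkh2-TAP, 795148 for Sak1-TAP and 906632 for Sep1-TAP. The scaling of tag counts to the control implies about 486279 control tags, or a mean of 5.98, 9.06 and 8.05 control tags per peak width in the 3 lists. A control count of 0.5, the lowest value listed, stood behind the fold in 13 Fkh2 peaks and 3 Sak1 peaks, so those folds rest on almost no control tags. Exact binomial 95% intervals are given for shares of peaks and cover counting error only.

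Coordinates are those of the deposited files, which name no build. They were read against the S. pombe assembly ASM294v3 with its RefSeq annotation of 5113 nuclear protein-coding genes. The fit of coordinates to this assembly was checked with the forkhead word GTAAACA, which lay within 150 bp of the centre of 112 of 152 Fkh2 peaks and of at most 19 when all peaks were shifted by 1000 to 5000 bp in steps of 500 bp. A gene was assigned to a peak when its annotated 5′ end lay in reach, that is when the peak centre was from 1000 bp upstream to 250 bp downstream of it. A single mitochondrial peak was left out of all tests against the nuclear genome.

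Overlap of at least 1 bp was tested one-sided against 100000 random placements in which each peak of the shorter list moved to a random gene 5′ end and kept its offset. Position relative to genes was tested two-sided against 100000 uniform placements. Membership in 13 gene lists was tested with Fisher's exact test, two-sided, over 39 tests. Presence of 4 preset words within 150 bp of the centre was tested one-sided against 10000 placements near other gene starts, over 12 tests, and all 7-base words were searched against 20 placed windows per peak. Ranks within a list were compared by permutation tests with 100000 resamples, or exactly where a side had under 10 peaks. P-values were adjusted by Benjamini-Hochberg within each family, with a threshold of 0.05. The gene lists, words, tests and most alternatives were fixed before the data were examined. The gene lists were written from general knowledge of fission yeast, and the M-phase list was written as a forkhead cluster. Genes and peaks named in the text are those in all 3 lists, the 10 peaks with the highest normalised tag count in each list and list members assigned to peaks in at least 2 lists; where the text names others, it says so. A peak with no gene start in reach is named by its nearest gene start.

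The tests of overlap, gene lists, words and peak strength and the repeat search were checked on simulated data; those of position, centre distance and carried-over DNA, and those of words or gene lists by sharing, were not. Of 100 random pairs of lists with 46 moved peaks, 5 fell below the overlap threshold, and all 100 pairs with 6 seeded shared peaks did. Among 100 random gene sets drawn from 5113 genes, 3 had a list that passed, and a list with 5 seeded members passed in all 100. A word planted in 14 of 46 windows passed in 19 of 20 runs, and no word passed in 20 runs without one. The alternatives comprised stricter peak thresholds, other definitions of overlap, reach and window, uniform placement, other words, another ranking measure and another list test. The barcode sheet was not used here. A gene, with the gene list and comparison word that go with it, is not reported here, but both stayed in the adjustment for multiple tests. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, Matplotlib 3.10.9 and BLAST 2.17.0 were used.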

Results

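Binding of the forkhead factors Fkh2 and Sep1 and of the RFX-family factor Sak1 was mapped by ChIP-seq in fission yeast cultures. Each tagged strain gave 1 peak list against the same untagged control, with 2 experiments pooled, so differences between lists carry no replicate error. The Fkh2 list held 152 peaks of 155 bp, the Sak1 list 47 peaks of 235 bp and the Sep1 list 11 peaks of 209 bp. These peaks held 1.93%, 0.965% and 0.110% of the tags of their libraries. By the authors' peak caller, the median fold over the untagged control was 10.6 in the Fkh2 list (range 4.01 to 372), 18.3 in the Sak1 list (5.25 to 369) and 9.11 in the Sep1 list (5.90 to 53.6). Before filtering, the caller had listed 5476 putative Fkh2 regions, 1109 Sak1 regions and 2398 Sep1 regions, of which the comparison with the untagged control removed 4969, 907 and 2113. The labels name bortezomib treatment for the Sep1 sample and give none for the others, so the short Sep1 list cannot be set against the others as a difference between factors alone.

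The strongest Fkh2 peak lay between protein-coding genes, 121 bp upstream of ecm33, which encodes a cell wall protein (chromosome I, 1571633 to 1571787). It had a normalised tag count of 6836 (per 10000000 tags) and 83.6 fold over the control. Its centre lay over an annotated long noncoding RNA gene. A separate Fkh2 peak 688 bp upstream of ecm33 (I, 1572200 to 1572354) ranked 3, with a count of 4665, and was not matched in the other lists. The Fkh2 peak upstream of mde6 and pun1 (I, 3696435 to 3696589) ranked 2, with a count of 6668. The Sak1 peak at the same place (I, 3696390 to 3696624) headed the Sak1 list, with a count of 4402. Its fold was 9.78, below the list median of 18.3, over 22 control tags, the highest control count in that list. The other Fkh2 peaks among the first 10 lay at knh4, cts2, SPCC306.11, gas1, gto1 and ubp11 and within the coding sequence of SPCC1840.13. The first 10 Sak1 peaks lay at mde6, ecm33, rep2, wdr8, mug122, uds1, gas1, cts2, knh4 and bet1, with counts of 2918 to 4402. The Sep1 list was headed by the promoter of psy1, a plasma membrane syntaxin gene (III, 1029249 to 1029457, in the annotated 3′ UTR of naa40), with a count of 2206 and 53.6 fold. It was followed by ecm33, with a count of 1754 and 17.0 fold. In the plot of ordered tag counts the peaks found in all 3 lists stand toward the left of the Fkh2 panel.

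**Figure D1:**
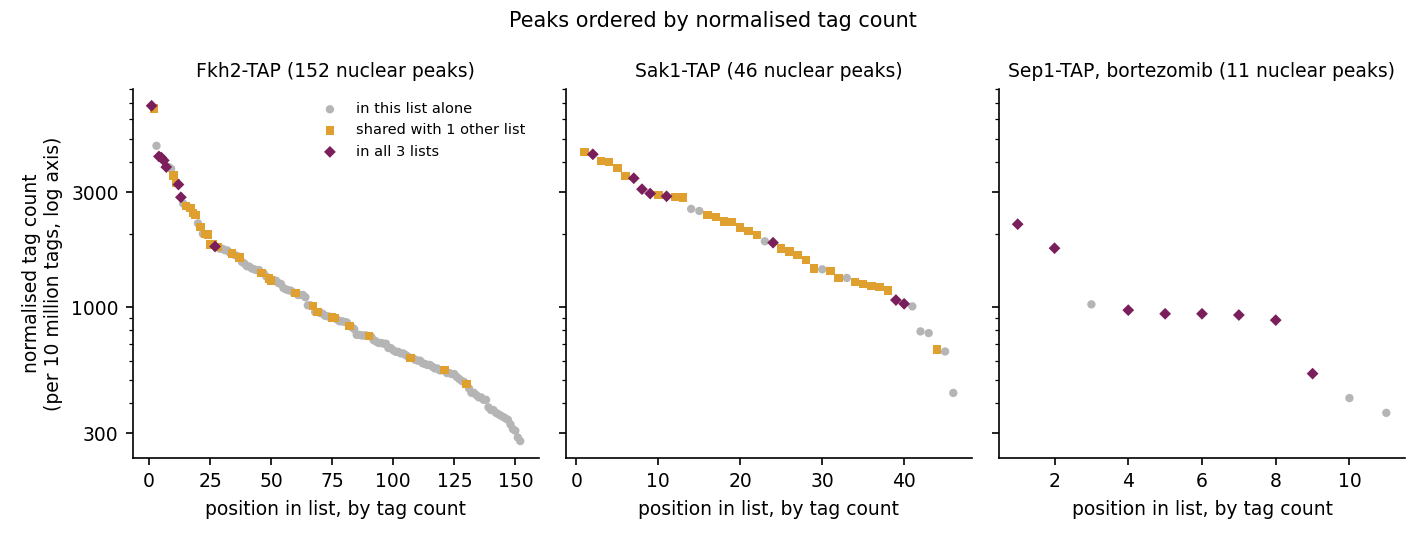
Normalised tag count (per 10000000 tags, log axis) of each nuclear peak against its position in its list, for Fkh2-TAP (152 peaks), Sak1-TAP (46) and Sep1-TAP with bortezomib (11); marker shape and colour show whether a peak was shared with other lists. Of the 8 Fkh2 peaks also found in the other lists, the strongest had a count of 6836 and the weakest, at psy1, 1783.

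Most Sak1 peaks lay at Fkh2 peaks, while most Fkh2 peaks had no Sak1 peak. Of the 46 nuclear Sak1 peaks, 36 overlapped a Fkh2 peak (78.3%, 95% interval 63.6 to 89.1), and these made up 23.7% of the Fkh2 list. These 36 included the promoters of the polo kinase gene plo1, cdc25 (the phosphatase that activates Cdc2), the ring component gene cdc15 and rep2, a coactivator gene of G1/S transcription. At plo1 the fold was low, 5.89 over 16.5 control tags for Fkh2 and 5.25 over 18.5 for Sak1. The latter was the lowest fold in the Sak1 list. Of the 11 Sep1 peaks, 8 overlapped peaks of both other lists, including those at psy1, ecm33, cts2, exg1, SPCC306.11, gas1 and knh4. Of these, gas1 and exg1 encode glucan-modifying cell wall enzymes and cts2 is annotated as a chitinase. The 10 nuclear Sak1 peaks with no Fkh2 peak, named here because they fall outside the 36, lay at mus81, qtr1, top1, slp1 with eng1, ght8, mae2, pgm1, hxk2 and at 2 places with no gene start in reach.

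Placement at random gene starts gave a mean of 0.677 shared peaks for Sak1 with Fkh2, 0.128 for Sep1 with Fkh2 and 0.0604 for Sep1 with Sak1. None of the 100000 placements reached the observed count in any of the 3 pairs (adjusted p = 1e-05 each, permutation test, the smallest they can give). At the level of genes, 45 genes had both a Fkh2 and a Sak1 peak in reach, against 1.53 for independent lists of 145 and 54 among 5113 genes. All lists share 1 untagged library, which could not be split, and part of the excess may come from it. In 100 simulated pairs of unchanged libraries against a common control, with an uneven background, the highest number of shared calls was 0. Those libraries had a mean of only 0 Fkh2 and 0.02 Sak1 calls, so the simulation does not show how much a common control adds to lists of this length. With the Fkh2 list shortened to as many peaks as the Sak1 list, 52.2% of Sak1 peaks overlapped. Centres of shared peaks lay a median of 28 bp apart for Sak1 and Fkh2 (quartiles 7.75 and 43 bp, largest 180 bp), 28 bp for Sep1 and Fkh2 and 48.5 bp for Sep1 and Sak1.

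**Figure D2:**
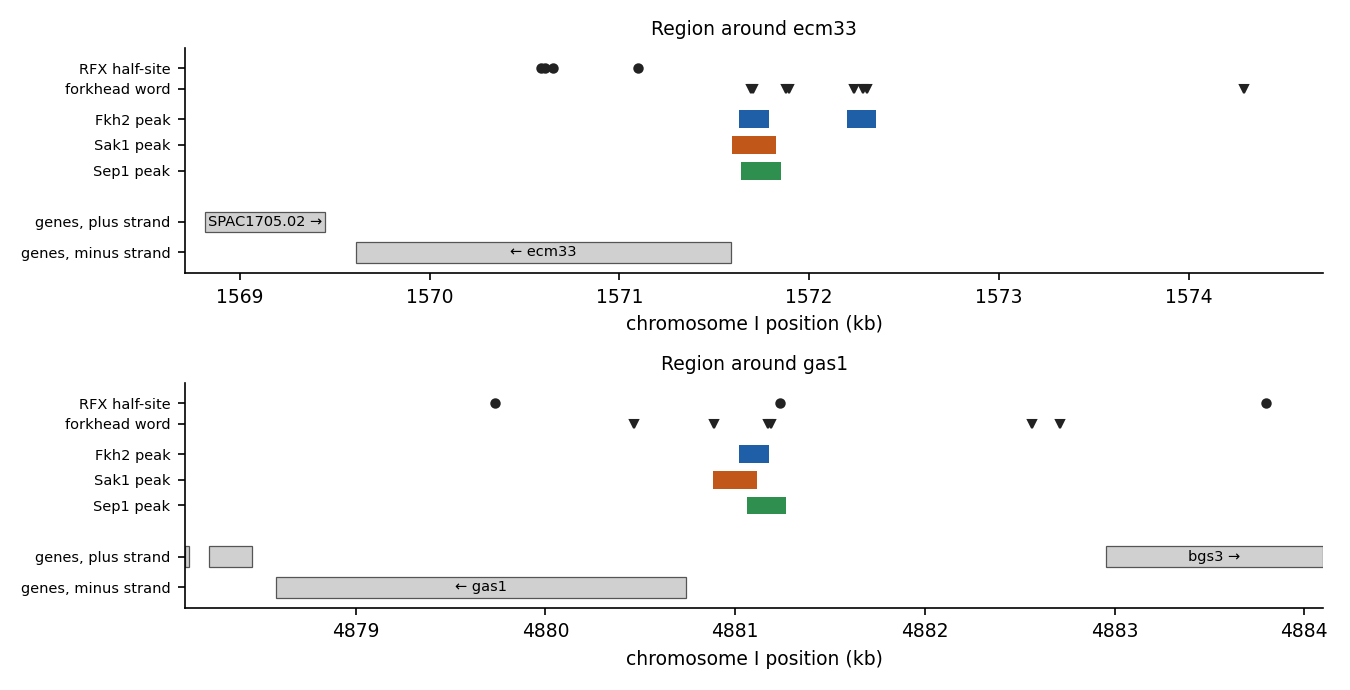
Maps of the regions around ecm33 and gas1 on chromosome I (position in kb), with annotated protein-coding genes by strand, the peaks of the 3 lists as bars, and forkhead words GTAAACA (triangles) and RFX words GTTRCCA (circles). Peaks of all 3 lists overlap upstream of both genes, and a Fkh2 peak with its centre 688 bp upstream of ecm33 stands apart.

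Peaks shared with another list were the stronger ones within the Fkh2 list. The 36 Fkh2 peaks shared with Sak1 had a median normalised tag count of 1817 (quartiles 1112 and 2944.7), against 740.6 (532.1 and 1188) for the 116 others (permutation test, two-sided, adjusted p = 1.5e-05). The 8 shared with Sep1 had a median of 3931 against 865.3 for the 144 others (exact permutation test, adjusted p = 6.7e-08). The 36 Sak1 peaks shared with Fkh2 had a median of 2100.2 against 1163 for the 10 others (permutation test, adjusted p = 0.0085), but ranked by fold over the control the difference in mean rank was 0.256 places in the other direction (p = 0.96). Peaks are not replicates, so these tests describe order within a list.

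Peaks of all 3 factors lay between protein-coding genes more often than uniform placement gave. Long noncoding RNA genes were not counted as genes here, and the centres of many of these peaks lay over them. The share was 63.8% for Fkh2, 78.3% for Sak1 and 81.8% for Sep1, against 23.4 to 23.6% for placed peaks (adjusted p = 4.5e-05, 4.5e-05 and 3.2e-04, placement permutation test, two-sided). A gene start was in reach of 116 of 152 Fkh2 peaks (76.3%) and 43 of 46 Sak1 peaks (93.5%), against 41.5% of placed ones (adjusted p = 4.5e-05 each), and of 8 of 11 Sep1 peaks (72.7%, permutation adjusted p = 0.11). For Sep1 the call for peaks between protein-coding genes was lost in the upper 50% of peaks (permutation adjusted p = 0.097). Gene starts passed for Sep1 with a reach of 500 bp upstream and 0 downstream (permutation adjusted p = 3.9e-04). The median peak centre lay 71.5 bp upstream of the nearest gene start for Fkh2, 67.5 bp for Sak1 and 134 bp for Sep1. A tRNA gene lay within 500 bp of 1 peak in each list, which did not differ from placement. The genes fkh2, sak1 and sep1 themselves had no start in reach of any peak.

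M-phase genes were the list with the most members bound by both Fkh2 and Sak1. The list was written as the forkhead cluster of M-phase transcripts, so its enrichment at Fkh2 peaks is not an unbiased result about M-phase genes. Fkh2 peaks were in reach of 11 of 27 genes of the list of M-phase transcripts (among them ark1, cdc15, cdc25, chs2, imp2, klp5, mde6, myp2, plo1 and spo12; 40.7% against 2.63% of other genes, adjusted p = 1.1e-09, Fisher's exact test) and Sak1 peaks of 10 (37.0% against 0.865%, adjusted p = 2.1e-12). Of these, 9 genes were bound by both, ark1 and chs2 by Fkh2 and not Sak1, and slp1 (the Cdc20-type activator of the anaphase-promoting complex) by Sak1 and not Fkh2. Members of the fixed lists with a peak in 1 list, here and in the next paragraphs, were chosen after their values were seen.

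Genes of the contractile ring and septum had peaks of both factors at cdc15, cdc4 (a myosin light chain), imp2 and myp2 (a myosin heavy chain), and of Fkh2 at chs2 (Fkh2 5 of 19, adjusted p = 9.4e-04; Sak1 4 of 19, adjusted p = 4.7e-04, Fisher's exact test). The Fkh2 peak at myp2 was weak, ranked 130 of 152 at 4.66 fold, and lay in the coding sequence 180 bp downstream of the start. Its centre and the Sak1 centre were 180 bp apart, the largest distance among the shared peaks of these factors. The list of mitotic entry, anaphase-promoting complex and exit genes had 3 of 16 members bound by Fkh2 (apc10, cdc25 and spo12, Fisher's exact adjusted p = 0.031) and 3 by Sak1 (cdc25, slp1 and spo12, adjusted p = 0.0032). The cell-cycle transcription factor list passed for Fkh2 (3 of 14, with cdc10 and rep2 among them, adjusted p = 0.028) and Sak1 (2 of 14, with rep2 among them, adjusted p = 0.031), by the same exact test.

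The Fkh2 list also reached 5 of 16 G1/S targets of the MBF factor (cdt1, dut1, mik1, rad21 and ssb1, Fisher's exact adjusted p = 4.7e-04). It reached 4 of 17 highly transcribed genes of glycolysis and translation (the glycolytic genes gpd3, gpm1, pyk1 and tpi1, adjusted p = 0.0054) and 3 of 15 genes of protein kinase A signalling and sexual differentiation (map2, mei2 and ste6, adjusted p = 0.031, Fisher's exact test). Sak1 peaks reached 1, 0 and 0 members of these lists, and the differences between factors were not tested. The MBF targets mik1 and ssb1 were reached by the same Fkh2 peak. The 5 genes thus stand for 4 peaks, of which 2 held the forkhead word. No list of the SIN pathway, spindle, histone, stress or ribosomal protein genes passed for any factor, with 0 of 10 histone genes and 3 of 141 ribosomal protein genes in reach of Fkh2 peaks. Several lists overlap, so the counts are not independent. With peaks placed at random in place of Fisher's test, the calls of Fkh2 protein kinase A and mitotic entry genes, and of Sak1 transcription factor genes, were lost (permutation adjusted p = 0.071 each). With a reach of 500 bp upstream and 0 downstream, Fkh2 transcription factor, protein kinase A and mitotic entry genes no longer passed (Fisher's exact test, adjusted p = 0.087, 0.092 and 0.097). In the upper 50% of peaks by tag count, the same 3 Fkh2 lists (adjusted p = 0.074, 1 and 0.088, exact test) and Sak1 ring genes (adjusted p = 0.25) did not pass.

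**Figure D3:**
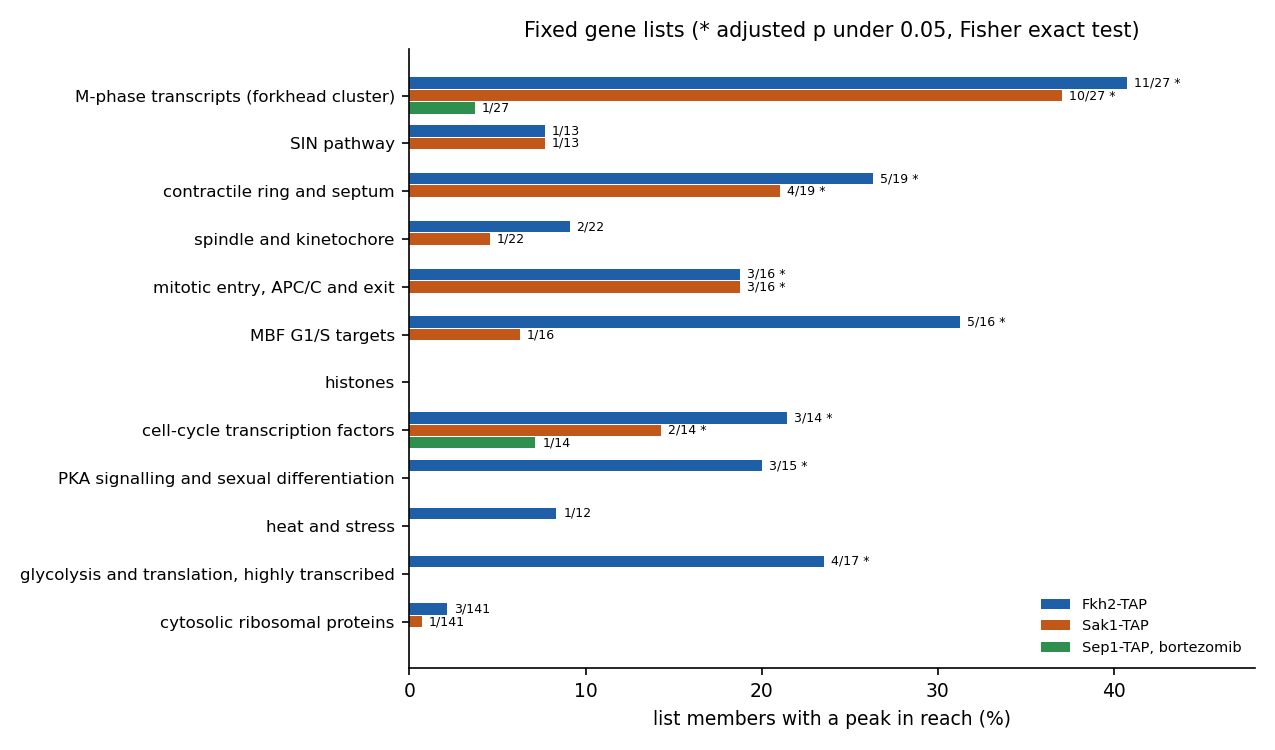
Percent of the members of the fixed gene lists reported here with a peak in reach of their start, for the 3 factors, with the number bound of the members beside each bar; an asterisk marks adjusted p under 0.05 (Fisher's exact test). M-phase transcripts had 11 of 27 members for Fkh2 and 10 for Sak1.

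The forkhead recognition word was common at the peaks of all 3 factors, Sak1 included. GTAAACA lay within 150 bp of the centre in 73.7% of Fkh2 peaks, 71.7% of Sak1 peaks and 63.6% of Sep1 peaks, against 12.1%, 13.8% and 13.2% of placed peaks (adjusted p = 2e-04 each, permutation test, the smallest they can give). The RFX word GTTRCCA lay at 15 of 46 Sak1 peaks (32.6% against 4.87%, adjusted p = 2e-04), 22 of 152 Fkh2 peaks (14.5% against 5.22%, adjusted p = 2e-04) and 3 of 11 Sep1 peaks (27.3% against 5.18%, permutation adjusted p = 0.022). In a comparison chosen after the overlap was seen, the RFX word lay at 14 of 36 Fkh2 peaks shared with Sak1 and at 8 of 116 others (Fisher's exact test, adjusted p = 1.2e-04). The forkhead word lay at 28 of 36 and 84 of 116 (exact test, adjusted p = 0.89). At Sak1 peaks it lay at 29 of 36 shared with Fkh2 and 4 of 10 others (exact test, adjusted p = 0.079). The MCB word ACGCGT, a comparison word, lay at 11.2% of Fkh2 peaks (2.53% placed, permutation adjusted p = 2e-04) and at 8.70% of Sak1 peaks (2.80% placed, adjusted p = 0.044). The Sak1 call for MCB was lost within 75 bp and in the upper 50% of peaks (permutation adjusted p = 0.17 each), and the Sep1 call for RFX with a degenerate word (permutation adjusted p = 0.12).

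**Figure D4:**
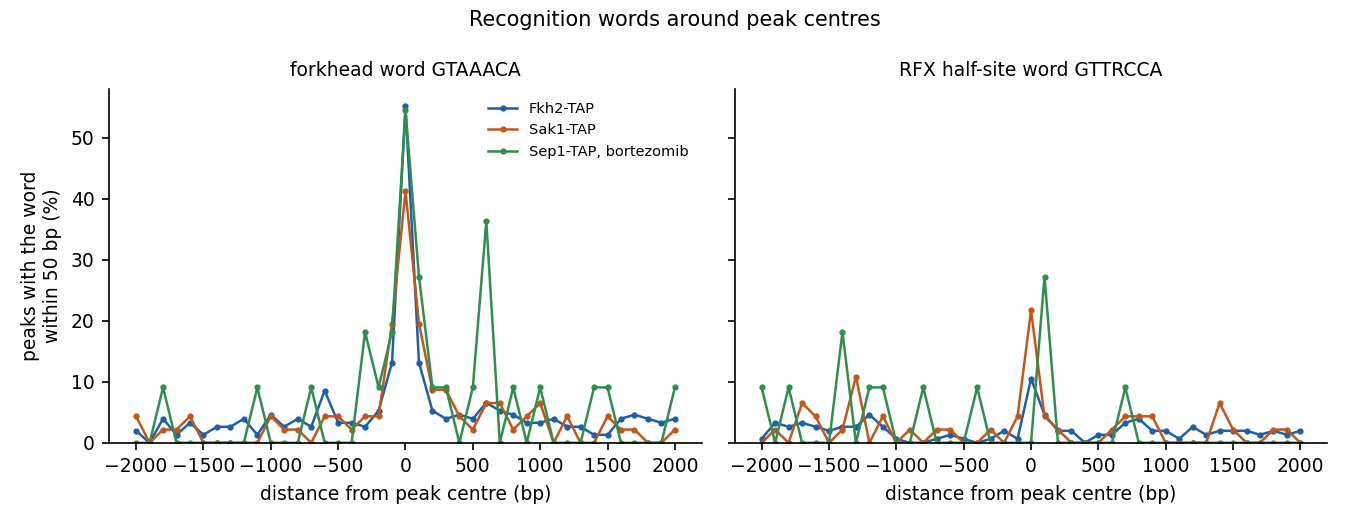
Percent of peaks with the forkhead word GTAAACA (left) or the RFX word GTTRCCA (right) within 50 bp of a point, against the distance of that point from the peak centre along the chromosome (bp), for the 3 lists. At the centre the forkhead word was found in 55.3% of Fkh2, 41.3% of Sak1 and 54.5% of Sep1 peaks, and each step of the Sep1 line is 1 of 11 peaks.

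In the search over all 7-base words, 48 words passed at Fkh2 peaks, 23 at Sak1 peaks and 1 at Sep1 peaks (Fisher's exact test, one-sided, each word against placed windows). GTAAACA ranked first in the Fkh2 list (exact test, adjusted p = 1.3e-60) and in the Sak1 list (adjusted p = 1.4e-13). At Sak1 peaks the words GTTGTCA and GTTGCTA each lay at 16 of 46 peaks (34.8% against 2.39% and 4.24% of placed windows, exact test, adjusted p = 9.5e-10 and 6.0e-07), and GTTGCCA, a form of the preset RFX word, at 10. The word that passed at Sep1 peaks was GTTGCTA, at 6 of 11 (exact test, adjusted p = 0.027), and 8 of these 11 peaks were also Sak1 peaks. At a word length of 6 no word passed at Sep1 peaks (exact test, lowest adjusted p = 0.75), and within 75 bp 3 words passed, with GTAAACA first (exact test, adjusted p = 0.0011). Fkh2 peaks also held ACGCGTC, at 12 of 152 (7.89% against 1.12%, exact test, adjusted p = 5.3e-04).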

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

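The tests in this part were chosen after the overlap and the peak positions were seen, except the search for long repeats. The Sak1 list contained a peak on the mitochondrial chromosome (19066 to 19300, within the annotated coding sequence of cox2), where no comparison was made, at 13.3 fold over the untagged control with a normalised tag count of 1094 and 4 control tags. It ranked 39 of 47, and neither other list had a mitochondrial peak. No explanation was tested.

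Fkh2 and Sak1 peaks coincided at 36 places. Few control tags at the shared places would not produce it: with the control raised to its genome-wide mean, 79.1% of the remaining Sak1 peaks still overlapped a Fkh2 peak. Genes prone to nonspecific pull-down were rare among the shared peaks, with 2.78% (1 of 36, upper 95% limit 14.5%) having a tRNA, glycolytic, translation or ribosomal protein gene in reach, although strongly transcribed genes outside those lists were not covered. Fkh2 DNA in the Sak1 library, as the whole cause, would leave few strong Fkh2 peaks without a Sak1 peak, but 29.2% of Fkh2 peaks above the median tag count of the shared ones had none (7 of 24, exact 95% interval 12.6 to 51.1%) and Sak1 DNA in the Fkh2 library could not give more tags per library there than in the Sak1 library, as 25% of shared peaks had beyond counting error (9 of 36, 12.1 to 42.2%, exact binomial tests; SPCC306.11 had normalised counts of 4056 and 1031). Among those 7 peaks, ubp11 and pyk1 had 17.5 and 15.5 control tags, which makes a 4 fold Sak1 call harder there, although Sak1 peaks had up to 22. The RFX word was enriched at the shared Fkh2 peaks with an odds ratio of 8.59, as it would be if Sak1 occupied those forkhead sites that hold its own word. This hypothesis was found and tested on the same data. A smaller carry-over that made part of the overlap was not excluded. Tag counts at the 36 shared peaks were correlated between the libraries (Spearman 0.39, permutation p = 0.019), which cannot separate carry-over from binding of both factors.

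The 3 Sep1 peaks outside the other lists had no gene start in reach: II, 4535465 to 4535673, which lies 4.13 kb from the chromosome end; III, 1097675 to 1097883, in a stretch of 78.2 kb without protein-coding genes that holds tRNA genes; and I, 58646 to 58854, in the pseudogene SPAC977.13C. In the order given, they ranked 3, 10 and 11 of 11, with normalised tag counts of 1026, 419 and 364. Their folds over the control were 7.12, 20.4 (over 1 control tag) and 5.9. GTAAACA lay at 7 of 11 Sep1 peaks and 7 of the 8 with a gene start in reach, so at none of these 3. Misplaced tags from long repeats of the assembled nuclear chromosomes do not account for these 3 peaks. There, 0 of the 3 had another copy (90% identity over 80% of the peak), in a search that found all 20 planted copies. Copies missing from the assembly could not be found this way. Short repeats may still contribute to the subtelomeric peak: 1 of the 3 had matches of at least 40 bp elsewhere, 8 in number and at most 49 bp long, while none of the 8 shared peaks had one. What keeps this open is that read placement cannot be seen in a peak list. The Fkh2 peak ranked 137 (II, 4536577 to 4536731) lay in the same stretch without protein-coding genes as the subtelomeric Sep1 peak, without overlapping it. Its fold of 4.01 was the lowest in the Fkh2 list. A Sak1 peak (II, 1601722 to 1601956, 31.8 fold) lay in a stretch of 51.5 kb without protein-coding genes, within 500 bp of a tRNA gene. No biological explanation was tested for any of these peaks.

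Fkh2 peaks at 4 glycolytic genes (pyk1, gpm1, gpd3 and tpi1) could be highly transcribed genes called without a forkhead site. The forkhead word was present at 100% of them (4 of 4, exact 95% interval from 39.8%, against 12.1% for placed peaks, exact binomial p = 2.1e-04), which argues against calls made without a site. The pyk1 peak had 15.5 control tags (8.49 fold), against a list median of 4. The peaks at gpm1, gpd3 and tpi1 had 3, 4 and 4. The gpm1 peak lay in the coding sequence of mug106, whose start was nearer (289 bp) than that of gpm1 (472 bp). With 4 peaks and no transcript levels, a part played by transcription stays open, and no biological explanation was tested.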

How the results depend on the processing

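No paired analysis was possible because each group has 1 pooled sample, and no replicate could be left out. The overlap of Sak1 with Fkh2 stayed above every placement under all 8 alternatives, at 52.2% (Fkh2 list shortened to the length of the Sak1 list) to 81.4%. The forkhead word stayed past the threshold in all 3 lists under all 5 alternatives (52.2% to 90.9% of peaks). The upper end came from the degenerate word, which 46.6% to 51.2% of placed peaks also held. Requiring 2 times the lowest fold left 101 Fkh2 and 5 Sep1 peaks, and the upper 50% by tag count left 76 Fkh2, 24 Sak1 and 6 Sep1 peaks by construction; both left 4 Sep1 peaks in all 3 lists. In the upper 50%, Sep1 peaks between protein-coding genes (66.7%) and the Sak1 word MCB (8.33%) were no longer past the threshold. Nor were Fkh2 mitotic entry genes (12.5%), Fkh2 transcription factors (14.3%) and Sak1 ring genes (5.26%). Fkh2 protein kinase A genes fell to 0%, below other genes, as the peaks at map2, ste6 and mei2 ranked only 81, 93 and 126. With a reach of 500 bp upstream and 0 downstream, Sep1 gene starts in reach (72.7%) passed, and Fkh2 mitotic entry (12.5%), transcription factor (14.3%) and protein kinase A genes (13.3%) did not. Random placement in place of Fisher's test ended the calls of Fkh2 mitotic entry (18.75%), Fkh2 protein kinase A (20%) and Sak1 transcription factor genes (14.3%). A 75 bp window ended the Sak1 call for MCB (4.35%), and the degenerate RFX word the Sep1 call (54.5%). Words passing at Sep1 peaks numbered 0 at 6 bases and 3 within 75 bp. Ranked by fold, Sak1 peaks shared with Fkh2 lay 0.256 places lower than the others, the reverse of the order by tag count. Except for shorter lists, the cause was not tested. About 486279 control tags, with a median of 4 to 5 at a peak, limit the precision of every fold. The Fkh2 list shortened to the Sak1 length, the raised control and the restriction to peaks near gene starts were chosen after seeing the data.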

Other observations

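The tests in this part were chosen after their results were seen, except those of the distance between centres and words and of the strength of peaks without a forkhead word, which were chosen after the peak lists but before their own results were seen. Genes of cell wall synthesis and remodelling recurred at the peaks. Of 33 genes whose annotated product names glucan, the cell wall or chitin, 6 had a Fkh2 peak (ags1, chs2, cts2, exg1, gas1 and gas5; 18.2% against 2.74% of other genes, Fisher's exact test, p = 2.8e-04), 6 a Sak1 peak (ags1, cts2, eng1, exg1, gas1 and gas5; p = 9.3e-07) and 3 a Sep1 peak (cts2, exg1 and gas1; exact p = 2.0e-05). The genes ags1, chs2, eng1 and gas5 are named here as members of this set, outside the rule for named genes. Membership came from product names, but the theme came from the peaks, so the test is no independent evidence. Among the 9 tests of this family, these 3 had adjusted p-values of 4.1e-04, 4.2e-06 and 3.6e-05. The family includes a list of 32 cell wall enzyme genes written by hand after the peaks were seen, of which 30 were in the annotation, with 7 members at Fkh2 peaks, 7 at Sak1 peaks and 3 at Sep1 peaks.

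M-phase genes were unevenly divided within the Fkh2 list. Of the 36 Fkh2 peaks shared with Sak1, 9 had an M-phase gene in reach, against 2 of the 116 others (odds ratio 19, Fisher's exact test, adjusted p = 4.9e-04 over 13 lists). The ring and septum list gave 4 of 36 against 1 of 116 (exact test, adjusted p = 0.074). The 4 peaks at glycolytic genes were all among the 116, which did not pass (exact test, adjusted p = 0.83). Shared peaks were also the stronger ones, so sharing and strength are not separated here.

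A wider RFX-like word, GTTGYYA, written from the words that the search found at Sak1 peaks, lay at 35 of 46 Sak1 peaks (76.1% against 14.9% placed). Since it was chosen on these Sak1 peaks, its share there is inflated, and the choice favours the Sak1 side in the distance to it. At shared peaks the Sak1 centre was not measurably nearer to this word than the Fkh2 centre (mean difference -5.31 bp over 29 peaks, sign-flip permutation p = 0.58), nor the Fkh2 centre nearer to the forkhead word (mean difference 1.96 bp, Sak1 minus Fkh2, over 28 peaks, p = 0.77). With standard deviations of 45.2 and 34.3 bp, a shift of a few base pairs could not be seen.

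The 40 Fkh2 peaks without a forkhead word ranked 30.1 places lower on average than the 112 with it (median normalised tag count 637.6 against 1109.8, permutation p = 1.1e-04), which is consistent with some of them being calls near the threshold. The strongest without it were cts2, in all 3 lists, with a count of 4166 and a fold of 102 over 2 control tags, and gto1, in the Fkh2 list alone, with a count of 3806 and a fold of 372 over 0.5 control tags. Genes with mug or meu symbols, named from meiotic expression, were not shown to be over-represented: 3.64% of 110 had a Fkh2 peak against 2.82% of other genes (Fisher's exact test, p = 0.55).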
